A study of Mus musculus with 12 samples.

How the data were processed

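Gene expression was measured in hearts and kidneys of mice lacking the equilibrative nucleoside transporter mENT1 (gene Slc29a1) and of wild type mice, all on the FVB/N background per the labels. Each of the 12 RNA samples was hybridised to one Agilent mouse array with a single dye (Cy3). The 4 groups were knockout heart, wild type heart, knockout kidney and wild type kidney, with 3 arrays each.

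The authors deposited a scanner file per array and one table of processed values. The deposited scanner files hold intensity per spot, made with Agilent Feature Extraction 9.5.3.1 per the file headers. The submitters' notes give version 9.1. The processed signal in these files is an intensity after background subtraction and detrending of the array, with surrogate values for dim spots, and with no scaling between arrays per the file headers. The deposited table holds log2 values that the authors scaled per array and centred, probe by probe, on the median of the 6 arrays of a tissue. These properties were tested on the values: 100% of the probes had a median within 0.01 of 0 over the 6 arrays.

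The columns of that table were compared with the scanner files. Each of the 12 columns correlated across probes at 0.9998 or above with the scanner values of the array with the same letter and tissue but the other genotype. Its correlation with the array of its own name lay between -0.392 and -0.059. The comparisons used the scanner files, because their Slc29a1 signal is lower in the knockout arrays. Every direction of change below rests on that choice. With the labels of the table each change within a tissue would be reversed. The table served as an alternative, with its columns matched to the arrays they follow.

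The processed signals were set to log2 and shifted so that the 75th percentile of the probes of each array was 0. Spots marked as non-uniform or as population outliers were left out, and replicate spots of a probe were averaged. The arrays carried 43379 spots for 41174 probes that were not controls. Probe names were updated through a table of gene names, by accession for 22951 probes, by symbol for 6659 and by synonym for 3109, while 8455 kept the name in the files. A probe was tested in a tissue when it was well above background on all 3 arrays of at least 1 group. Where a gene had several probes, the one with the highest mean was taken. Probe positions are those of build mm7, per the file headers.

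Knockout was compared with wild type within each tissue with limma 3.58.1 in R 4.3.3, by a linear model with moderated variances, and p-values were adjusted with the Benjamini-Hochberg method. This main fit held no block for letter or slide and no covariate for sex. Calls, named genes, lists and neighbours come from it unless another fit is named. A gene was called at an adjusted p under 0.05. A fit of all 12 arrays gave the effect averaged over both tissues and the difference of the heart effect from the kidney effect. A total of 49 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, again with a correlation estimated per list, and with fry. Camera asks whether the genes of a list are shifted relative to the other genes. Lists with fewer than 3 members tested were left out. Overlap between tissues was tested with a hypergeometric test. The called share among the 50 tested genes on each side of Slc29a1 was set against other chromosomes with a one-sided Fisher's exact test. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so single genes rest on limma, which shares the variance across genes.

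The rule for naming genes was fixed before the data were examined. It takes, per tissue, Slc29a1, the 12 largest rises and 12 largest falls among called genes with a symbol and no overlap between the groups, and up to 4 members per direction from each list that passed over all genes or over the list alone. It also takes every nucleoside transporter and adenosine receptor above background. For the averaged effect it takes the 10 largest changes per direction and for the difference the 10 smallest adjusted p, both among genes with a symbol, and for the shared genes and the neighbours of Slc29a1 every called gene up to 12. Where a gene was not above background in one group, its fold is given as a lower bound. Some genes that the rule takes are not reported.

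The methods were tested on simulated data made from these arrays. Of 100 genes changed by 1 log2 unit, 29% were called in heart and 25% in kidney. Of 100 genes changed by 2 log2 units, 90% and 82% were called. Of the 130 genes called in the simulated heart 9 were false, and 6 of 114 in the simulated kidney. The list that had been raised was found in both, with 0 other lists. The simulated genes varied independently of each other, with no effect of slide, sex, letter or carried-over tissue. The simulation therefore does not measure how many false genes or lists the real arrays give.

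Sex was read from Xist and 4 Y-linked genes. The slide of each array was read from the file headers. All 3 knockout hearts lay on one slide together with wild type kidney c, and all 3 wild type hearts lay on another. Knockout kidneys b and c shared a slide with wild type kidneys a and b. Knockout kidney a lay alone on the slide numbered 1.

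The labels give the replicates letters without saying what the letters share. Deviations from the group means were compared across 22118 probes. For every letter, knockout and wild type heart deviated together, with correlations of 0.175 to 0.372 against a mean of -0.139 for unequal letters. Deviations cancel out within a group, so the negative mean for unequal letters follows from the positive values and is no separate evidence. Some matching of the letters must come out highest. In kidney equal letters correlated at -0.179 to 0.175. A pairing of the hearts by letter is thus read from the data and not established. It was used for an alternative block and for a choice of splits.

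Alternatives planned before the data were examined covered normexp background correction with an offset of 50, quantile and median scaling, the value table, filters, the treatment of several probes, a variance trend, joint fits, slide and replicate blocks, and leaving out each array in turn. Alternatives chosen after seeing the data were sex as a covariate, only the arrays without Xist signal, normexp without spots of bright local background, and the value table with its columns as named. Signal well above background covered 60.6% to 70.8% of the spots of an array, and the number of arrays limits the precision.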

Results

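The study compared gene expression between mice without mENT1, a transporter that lets nucleosides such as adenosine cross the cell membrane, and wild type mice. There were 3 arrays each of knockout heart, wild type heart, knockout kidney and wild type kidney. The 75th percentile of the intensity ran from 464 to 940.4 between arrays, and 157 to 331 spots per array were saturated. Values below are log2 signals relative to that percentile, and changes are knockout minus wild type with the standard error (SE) of the limma fit, from 3 arrays against 3 unless stated.

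The tissue of every array was checked with 8 heart genes, such as Myh6 and Tnnt2, and 8 kidney genes, such as Umod and Slc34a1. The median of the heart genes was 6.58 ± 0.25 (SD, n = 6) in hearts and -6.37 ± 0.23 (SD, n = 6) in kidneys. The median of the kidney genes was 6.15 ± 0.16 (SD, n = 6) in kidneys and -7.91 ± 0.93 (SD, n = 6) in hearts. No array lay nearer to the other tissue. Xist, the RNA of the inactive X chromosome, was at 1.70 on knockout heart a, 1.69 on knockout heart b and 1.21 on knockout kidney a. On those 3 arrays none of the 4 Y-linked genes was above background. On the other 9 arrays Xist lay at or below -7.97 and all 4 Y-linked genes were above background.

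Slc29a1, the targeted gene, was lower in both knockout tissues by the labels of the scanner files. Those labels were kept because of this fall, so its direction and p-values are no independent check of them. One probe measures it (A_51_P289836, chromosome 17, positions 43714823 to 43714882 of build mm7). In heart it stood at 1.17 in knockouts and 3.24 in wild types, a change of -2.08 ± 0.26 (SE, n = 3 and 3) with an adjusted p of 0.0362 by limma. That is a signal 4.22-fold lower. In kidney the change was -2.85 ± 0.16 (SE, n = 3 and 3) with an adjusted p of 0.00547 by limma, 7.21-fold lower. The probe stayed well above background on all 12 arrays, and whether it lies in the deleted part of the gene is not given in the files. The difference between the tissues was 0.77 with an adjusted p of 0.302 by limma. The heart call ended when knockout heart a (adjusted p of 0.111 by limma), wild type heart a (0.101), b (0.161) or c (0.190) was left out, and with the letters as a replicate block it ended at 0.0671. It also ended with quantile scaling (0.0579), no filter (0.0863), a filter on every array (0.0562), sex as a covariate (0.182) and only the arrays without Xist signal (0.0599). The kidney call ended without wild type kidney a (adjusted p of 0.0712 by limma) or c (0.0700), with the letter block (0.0744) and with normexp (0.701).

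**Figure D1:**
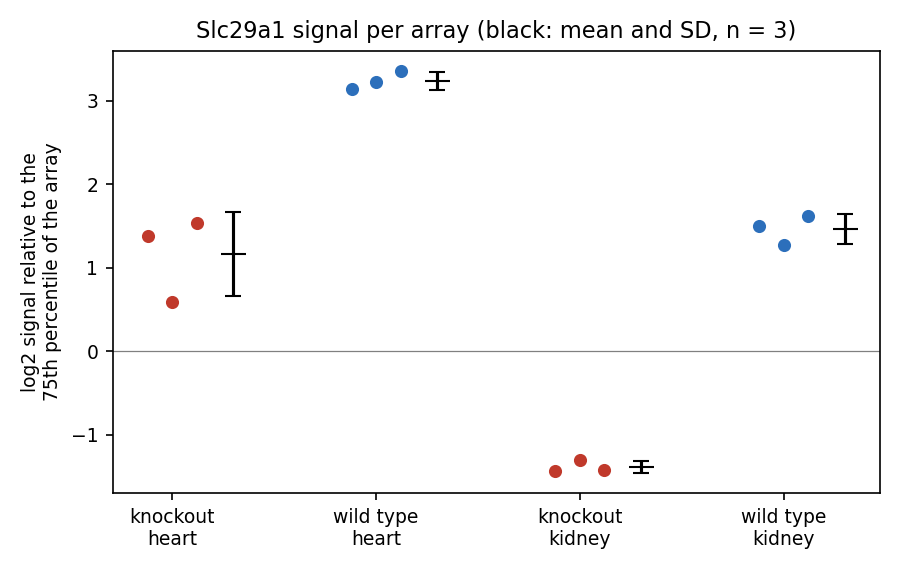
Slc29a1 signal of each array, in log2 units relative to the 75th percentile of the array, with the mean and SD of the 3 arrays beside each group. Knockout arrays lie below wild type arrays in both tissues, by 2.08 in heart and 2.85 in kidney on the log2 scale.

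Of the other nucleoside transporters and the adenosine receptors, none was called in either tissue. In heart Slc29a2 changed by -0.05 ± 0.26, Slc29a3 by -0.15 ± 0.19, Slc29a4 by -0.39 ± 0.31, Slc28a2 by -0.28 ± 0.13 and Slc28a3 by 0.93 ± 0.70 (SE, n = 3 and 3). Their adjusted p in limma ran from 0.332 to 0.926. The heart adenosine receptors gave -0.31 ± 0.30 for Adora1, -0.47 ± 0.20 for Adora2a, 0.59 ± 0.20 for Adora2b and 0.25 ± 0.21 for Adora3. Only 2 of 3 Adora1 probes and 1 of 2 Adora2a probes went in the direction given for heart. In kidney Slc29a2 changed by 0.30 ± 0.18, Slc29a3 by 0.62 ± 0.38 and Slc28a2 by -0.65 ± 0.35, and Adora1 by 0.26 ± 0.25, Adora2a by -0.07 ± 0.18 and Adora2b by 0.26 ± 0.23. The kidney value of Adora1 comes from another probe than its heart value. The list of nucleoside transporters did not pass with camera in heart (adjusted p of 0.188) or kidney (0.536). The list of adenosine receptors did not pass either (0.701 and 0.552).

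Among the genes raised in knockout hearts were transcripts that are abundant in liver. Cps1, the first enzyme of the urea cycle, changed by 4.58 ± 0.56 and F2, the precursor of thrombin, by 4.24 ± 0.57 (SE, n = 3 and 3), each with signal above background on 1 of 3 wild type hearts. Fabp1, the liver fatty acid binding protein, was 16.5-fold higher. Albumin (Alb) was 11.8-fold higher, from a level of -2.87 to 0.70. Dnah8, a dynein heavy chain of cilia and sperm tails, was 22.8-fold higher (4.51 ± 0.16), and H2-Eb1, a beta chain of MHC class II, 20.7-fold (4.37 ± 0.21). H2-Ea, an alpha chain of MHC class II, was at least 2.60-fold lower.

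Across the 17483 genes tested in heart, limma called 116 in the main fit, which does not pair the hearts by letter. Of these 101 rose and 15 fell, and 21 carry no gene symbol. At an adjusted p under 0.10 the count was 249, and 2743 genes had an unadjusted p under 0.05. Groups did not overlap for 22.1% of all genes, where chance gives 10%. Among the other named rises, Mbl2 was at least 13.5-fold higher, Hemgn at least 13.1-fold, Apom at least 9.47-fold, Aadac at least 6.89-fold and Oas1d at least 3.96-fold. Apoc3, above background on 1 of 3 wild type hearts, rose by 3.99 ± 0.44 and Cyp3a41a by 3.89 ± 0.28. The falls were Guca1a (7.94-fold lower), Tbx15 (2.95-fold), Vmn1r90 (3.01-fold), Pla2g7 (2.25-fold) and Cdh23 (2.14-fold). Trem1 (-1.24 ± 0.17) and Klhl1 (-1.19 ± 0.16) fell too, with signal above background on 1 and 2 of 3 knockout hearts. Tnip3 was at least 2.63-fold lower, Speer4b at least 1.72-fold and C1ql1 at least 1.41-fold. With the letters as a replicate block limma called 55 genes, 32 of them among the 116, and 10 of the 31 named calls other than Slc29a1 were kept, among them Dnah8, H2-Eb1, Apom, Aadac and Oas1d. With that block the adjusted p in limma was 0.0827 for Mbl2, 0.0612 for Cps1, 0.0963 for F2, 0.0506 for Fabp1 and for C1ql1, 0.054 for Apoc3, 0.105 for Alb and 0.112 for Guca1a. It ran from 0.0581 to 0.111 for Tnip3, Tbx15, Klhl1, Vmn1r90, Trem1, Pla2g7 and Cdh23. Slide and genotype cannot be told apart in heart.

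The hearts differed in sex and in the arrays that carry the changes. Knockout hearts a and b show Xist signal, while knockout heart c and the wild types do not. With only the arrays without Xist signal, 1 knockout against 3 wild types, limma called 46 genes; the lone knockout is assumed to vary like the wild types. Of the 31 named calls 6 were kept there: Dnah8 (4.41), H2-Eb1 (4.08) and 4 genes not above background in 1 group, namely Apom, Aadac and Oas1d, which rose, and Speer4b, which fell. Slc29a1 gave -1.71 with an adjusted p of 0.0599. Without knockout heart c the count of called genes was 1979, without knockout heart a 50, without knockout heart b 62, without wild type heart b 23 and without wild type heart c 31.

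**Figure D2:**
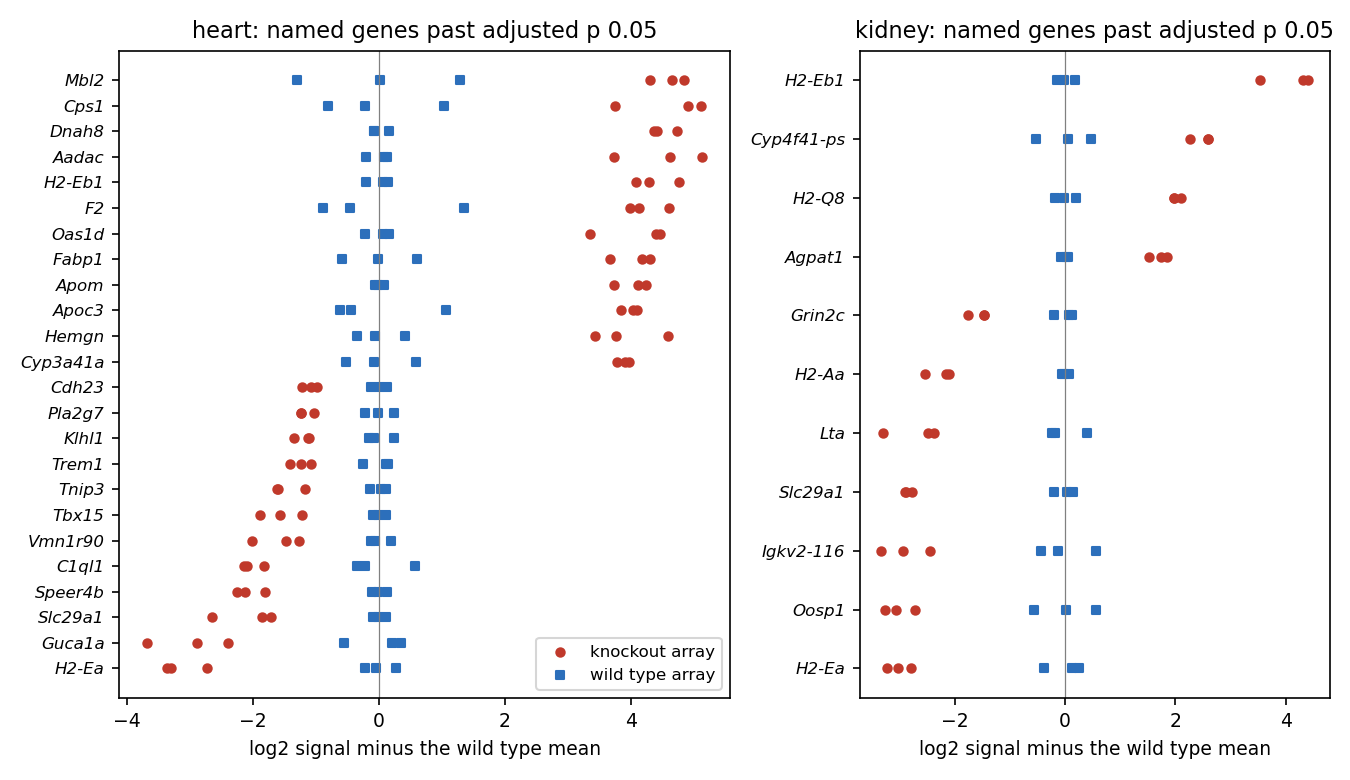
Log2 signal of each array minus the wild type mean, for the called genes with the largest rises and falls in heart (left) and kidney (right). Red points are knockout arrays and blue squares wild type arrays. H2-Eb1 lies higher and H2-Ea and Slc29a1 lie lower in the knockouts of both tissues.

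Of the 49 gene lists, 20 passed with camera in heart, 13 shifted up and 7 down. None passed with an estimated correlation, where their adjusted p ran from 0.650 to 0.694, and with fry 1 passed, that of pyrimidine metabolism (adjusted p of 0.0486). The list of liver and pancreas had 11 of 13 members higher, 6 of them called, with a median of 0.60 (adjusted p = 7.2e-07, and adjusted p = 0.650 with an estimated correlation). Adjusted over the list alone, 6 rose as well, among them Apoa2 (3.15 ± 0.28) and Apoc3 (3.99 ± 0.44). Single members of other lists that rose are also abundant in liver: Uox of purine breakdown (3.50 ± 0.41, above background on 1 of 3 wild type hearts), Fgg of the kidney injury list (3.27 ± 0.40) and Fbp1 of gluconeogenesis (3.19 ± 0.33). With the letter block the adjusted p in limma was 0.0581 for Apoa2, 0.0848 for Uox, 0.133 for Fgb and 0.101 for Fgg. In the list of heat shock and the unfolded protein response 18 of 24 members were higher, with Hspa1a (1.55 ± 0.17) and Dnaja1 (0.94 ± 0.12) called (adjusted p = 3.8e-05, and adjusted p = 0.650 with an estimated correlation). With the letter block their adjusted p in limma was 0.0574 and 0.104. Cholesterol synthesis genes were higher in 19 of 21 (median 0.43, adjusted p = 7.3e-05, and adjusted p = 0.650 with an estimated correlation), with medians of 0.83, 0.03 and 0.24 on knockout hearts a, b and c and 0.16 on wild type heart a, and MHC genes in 17 of 28 (median 0.28, adjusted p = 0.031, and adjusted p = 0.650 with an estimated correlation), with medians of 0.22, 0.52 and 0.14 on knockout hearts a, b and c and 0.21 on wild type heart a. Adjusted over the list alone, Ifi44 of the interferon list (1.08 ± 0.16) and Egr3 (0.92 ± 0.14) and Atf3 (0.66 ± 0.12) of the immediate early genes rose.

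Cell cycle and lymphocyte genes were higher in knockout hearts a and b, the arrays with Xist signal. All 29 cell cycle genes were higher, with a median of 1.60 and no member called (adjusted p = 7.8e-12 with camera, and adjusted p = 0.650 with an estimated correlation). Their median was 1.86 on knockout heart a, 2.85 on b and 0.00 on c. All 15 genes of the thymus and lymphocyte list were higher, with a median of 3.18 (adjusted p = 3.8e-07, and adjusted p = 0.650 with an estimated correlation), and medians of 3.75, 3.56 and 0.29 on knockout hearts a, b and c and 0.54 on wild type heart a. Dntt, a DNA polymerase of immature lymphocytes, stood at 5.65 and 6.71 on a and b and at -3.40 on c. The collecting duct list, which holds keratins, was higher in 8 of 8 members (adjusted p = 0.0081, and adjusted p = 0.650 with an estimated correlation) with medians of 1.76, 1.24 and 0.19. The lung and airway list had a median of 8.98 on knockout heart a, 0.19 on b and -0.40 on c, and 2.33 on wild type heart a (adjusted p = 0.032, and adjusted p = 0.650 with an estimated correlation).

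Several lists of heart muscle, vessels and matrix lay slightly lower, while the 8 heart genes of the tissue check did not pass (adjusted p of 0.246). In oxidative phosphorylation 55 of 59 members were lower with a median of -0.20 (adjusted p = 0.0092, and adjusted p = 0.694 with an estimated correlation). In contraction and calcium handling 25 of 26 were lower (-0.27, adjusted p = 0.010, and adjusted p = 0.663 with an estimated correlation). In atrial myocardium 10 of 10 (-0.47, adjusted p = 0.016) and in endothelium 17 of 17 (-0.34, adjusted p = 0.0013) were lower, as were 27 of 30 genes of extracellular matrix (-0.26, adjusted p = 0.010) and 12 of 13 of smooth muscle and pericytes (-0.27, adjusted p = 0.036), each with an adjusted p = 0.650 with an estimated correlation. No member of these lists was called. Their medians on knockout heart c were 0.00, -0.01, -0.09, -0.09, -0.02 and -0.09. In the first 3 lists wild type heart c stood highest of all hearts, with medians of 0.26, 0.30 and 0.34, and wild type heart b was at -0.21, -0.14 and -0.27, so 1 wild type array carried part of these shifts. For extracellular matrix wild type heart c was at -0.14, below knockout heart c. With arrays scaled by their median the median of all heart genes was -0.23 in place of -0.07, and changes of this size are relative to it.

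Among the genes called in knockout kidneys, 4 were MHC genes, 2 higher and 2 lower. H2-Eb1 was 17-fold higher (4.08 ± 0.26, SE, n = 3 and 3) and H2-Q8, a class I gene, 4.04-fold (2.02 ± 0.16). H2-Aa, an alpha chain of class II, was 4.80-fold lower (-2.26 ± 0.17) and H2-Ea at least 2.58-fold lower. Lta, a cytokine of lymphocytes, was at least 5.99-fold lower, and the immunoglobulin segment Igkv2-116 was 7.48-fold lower (-2.90 ± 0.33). Agpat1, an enzyme of phospholipid synthesis, was 3.25-fold higher and the pseudogene Cyp4f41-ps at least 4.09-fold. Grin2c, a subunit of the NMDA receptor, was 2.96-fold lower and Oosp1 at least 2.30-fold.

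Limma called 28 of 17228 genes in kidney, of which 5 rose and 23 fell, and 17 of them carry no gene symbol. At an adjusted p under 0.10 the count was 163, and 2266 genes had an unadjusted p under 0.05. Groups did not overlap for 21.5% of all genes, where chance gives 10%. Within the slide that held 2 arrays of each genotype, limma called 289 genes, 145 up and 144 down, and the joint fit called 77, 41 up and 36 down. In the fit within the slide Slc29a1 was at -2.75 (adjusted p of 0.0164 by limma), H2-Eb1 at 4.35 and H2-Aa at -2.14. All 10 named calls other than Slc29a1 were kept in that fit. Without knockout kidney a, the only kidney with Xist signal, the count was 121 and the same 10 were kept. The fits within the slide and without knockout kidney a both compare only knockout kidneys b and c with wild types. Clock genes were shifted on those knockouts (the clock output gene Dbp at 2.07 and 2.15 against 6.08 to 6.80 in wild types). Genotype and clock state therefore cannot be told apart in these fits. The count was 5 without knockout kidney b, 87 without c, 1 without wild type kidney a, 2 without b and 1 without c.

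In kidney 13 lists passed with camera, 6 up and 7 down, and none with an estimated correlation (adjusted p of 0.522 to 0.911). With fry 2 passed, MHC genes and nucleoside transporters, both at an adjusted p of 0.0216. The latter list holds Slc29a1 itself among its 4 tested members. Of the MHC genes 22 of 27 were lower, with a median of -0.59 (adjusted p = 4.4e-05, and adjusted p = 0.522 with an estimated correlation). Adjusted over the list alone, 4 MHC genes rose and 16 fell. Macrophage and neutrophil genes were lower in 14 of 18 members (median -0.54, adjusted p = 5.4e-04, and adjusted p = 0.704 with an estimated correlation). Adjusted over that list alone 6 fell, such as Adgre1, the macrophage marker F4/80 (-1.26 ± 0.21), and Mrc1, the mannose receptor (-1.16 ± 0.19). Inflammatory cytokines and adhesion genes were lower in 16 of 17 (median -0.56, adjusted p = 5.4e-04, and adjusted p = 0.704 with an estimated correlation), and the chemokine Ccl5 (-1.81 ± 0.28) and Vcam1 (-0.92 ± 0.22) fell over the list alone. Cell cycle genes were lower in 26 of 28 (median -0.75, adjusted p = 2.1e-08, and adjusted p = 0.704 with an estimated correlation), with 15 past the threshold adjusted over the list alone, Bub1, Ccnb1, Ccnb2 and Birc5 among them. Extracellular matrix genes were lower in 22 of 30 (median -0.35, adjusted p = 6.4e-04, and adjusted p = 0.911 with an estimated correlation), at a median of -0.19 on knockout kidney a and -0.20 on wild type kidney b. Col1a1 (-1.30 ± 0.23), Col3a1 (-1.10 ± 0.25) and Fbn1 (-0.99 ± 0.17) fell over that list alone.

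Epithelial genes of the kidney lay on either side. All 9 urothelium genes were higher (median 0.94, adjusted p = 5.3e-07, and adjusted p = 0.522 with an estimated correlation), and 7 rose adjusted over the list alone, among them the uroplakin Upk3a (0.97 ± 0.15) and Psca (1.04 ± 0.22). Glomerulus genes were higher in 10 of 12 (median 0.36, adjusted p = 5.4e-04, and adjusted p = 0.704 with an estimated correlation), where Nphs1, the slit diaphragm protein nephrin (1.12 ± 0.27), and Synpo (0.84 ± 0.16) rose over the list alone. Collecting duct genes were higher in 10 of 16 (adjusted p = 0.0056, and adjusted p = 0.911 with an estimated correlation), at a median of 0.79 on knockout kidney a, -0.00413 on b and 0.07 on c, with the water channels Aqp2 (1.29 ± 0.25) and Aqp4 (1.93 ± 0.49) past the threshold over the list alone. Proximal tubule genes were lower in 22 of 25 (median -0.26, adjusted p = 0.039, and adjusted p = 0.911 with an estimated correlation). Their medians were -0.32, -0.31 and -0.11 on knockout kidneys a, b and c and 0.02, 0.27 and -0.27 on the wild types, so wild type kidney b carried part of this shift. Slc12a3, the thiazide-sensitive sodium chloride transporter, gave -1.60 ± 0.31 (adjusted p of 0.115 by limma). Of the liver list 9 of 11 members were higher (median 0.53, adjusted p = 6.4e-04, and adjusted p = 0.704 with an estimated correlation), and over the list alone Apoa1 was at least 2.81-fold higher and Apoa2 changed by 3.17 ± 0.62, above background on 2 of 3 wild type kidneys. Its medians were 1.01, 0.39 and 0.04 on knockout kidneys a, b and c and 0.11 on wild type kidney b. The adrenal list had a median of 3.86 on knockout kidney a against 0.16 and 0.18 on b and c (adjusted p = 0.0056, and adjusted p = 0.911 with an estimated correlation).

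**Figure D3:**
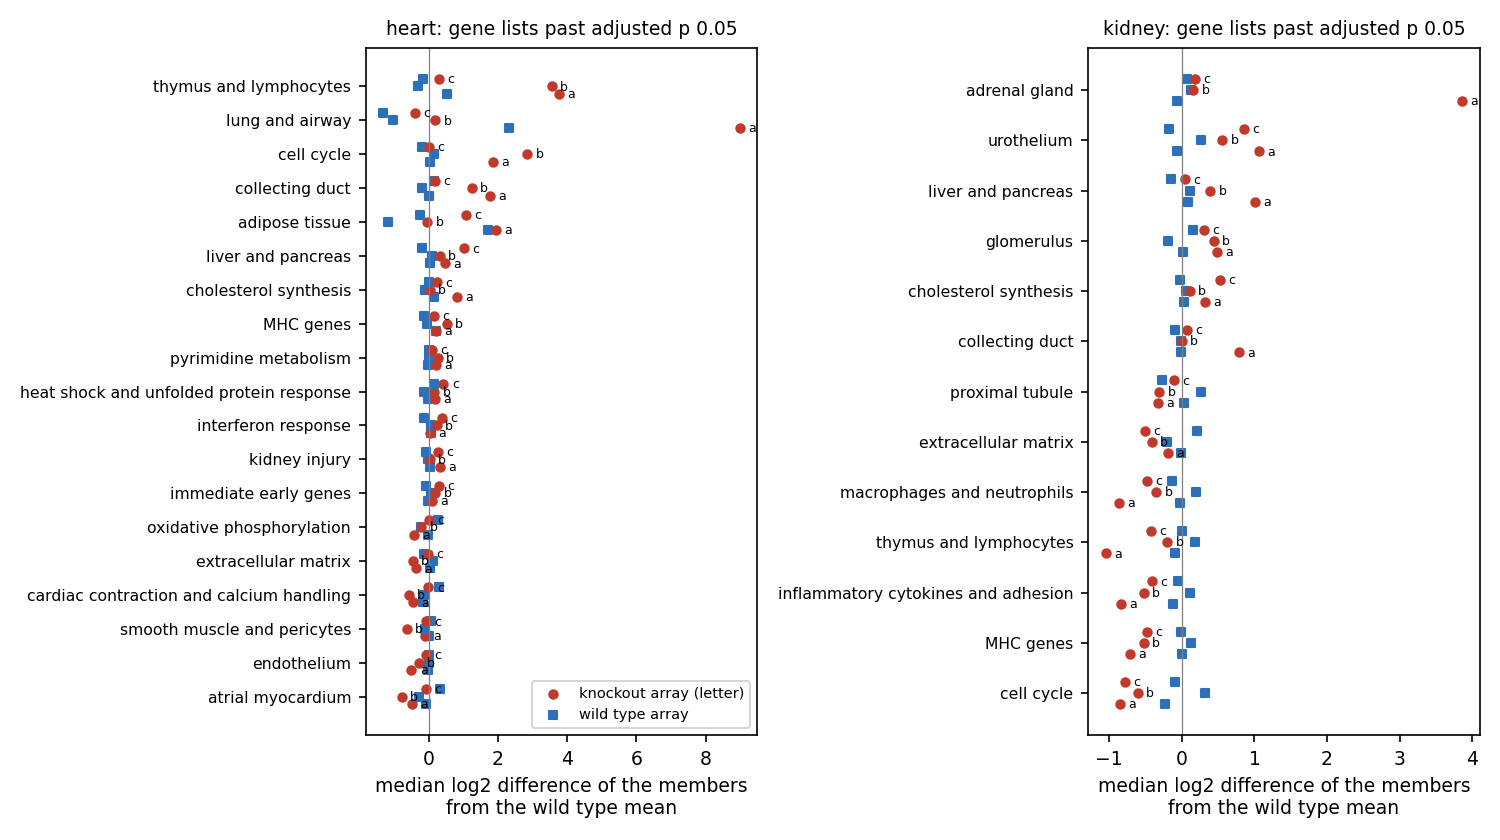
Median log2 difference of the members of each list from the wild type mean, per array, for the lists past the camera threshold in heart (left) and kidney (right), without the sex-linked genes. Red points are knockout arrays with their letter and blue squares wild type arrays. Thymus and lymphocyte genes stand at 3.75 and 3.56 on knockout hearts a and b and at 0.29 on c.

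Averaged over both tissues, limma called 192 of 18502 genes, 114 up and 78 down. Among the named rises, H2-Eb1 changed by 4.23 ± 0.18 (SE, n = 6 and 6), the major urinary protein genes Mup1 and Mup4 by 3.65 ± 0.62 and 3.54 ± 0.61, Apoa5 by 3.24 ± 0.62, Cyp3a41a by 3.19 ± 0.40 and Apoa2 by 3.16 ± 0.38. Cps1, Zfp33b, Mup5 and Uox rose as well, with no wild type kidney above background. Mup1, Mup4, Mup5 and Apoa5 were called in neither tissue alone. Mup1, Apoa5, Cps1 and Uox belong to the list of liver transcripts described below, and Apoa2 to the list of liver and pancreas. Mup1 lay 5.12, 4.77 and 1.71 above the wild type mean on knockout kidneys a, b and c. Among the named falls were Guca1a (-2.89 ± 0.31), Slc29a1 (-2.46 ± 0.16), H2-Aa (-1.67 ± 0.15), Pcdh7 (-1.62 ± 0.19) and the kinase Sik1 (-1.59 ± 0.19). H2-Ea fell too, with no knockout array above background. So did Vsig4, a macrophage receptor, Mir124-2hg, Vgll2 and Gabrb2, for which no knockout kidney was above background. Vgll2 and Gabrb2 were above background on no wild type kidney either, and Mir124-2hg on no heart. For these genes the average therefore rests on signal in 1 tissue. Of genes without a symbol, 5430410E06Rik changed by -3.69 ± 0.24, and BC023719 fell with no knockout array above background. With the slide as a random block the count was 79, with sex as a covariate 76. Leaving out 1 array gave 73 to 1254, the highest without knockout heart c and the lowest without wild type heart b. The count was 94 without knockout heart a, 125 without b, 114 without wild type heart a and 113 without c. It was 112 without knockout kidney b, and 86, 116 and 121 without wild type kidneys a, b and c.

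The knockout effect differed between heart and kidney for 117 genes, 103 with a higher change in heart. Of the named ones, Fbp1 and Amn were above background in all 4 groups, with differences of 3.40 ± 0.43 and 2.99 ± 0.30. Bhmt2, Apom, Aadac, Ugt3a1 and Cyp2c40 were above background on no wild type heart. They were at least 2.44-, 9.47-, 6.89-, 1.54- and 5.48-fold higher in knockout hearts, and their differences in kidney were -0.04, 1.17, -0.22, -0.36 and -0.02. Kap, above background on 2 of 3 knockout hearts and no wild type heart, was at least 1.15-fold higher there and at -0.19 in kidney. Dnah8 was above background on no kidney, so its change there is not measured. All but Dnah8 and Cyp2c40 of these genes stood at 4.22 or higher in wild type kidneys. With the slide as a random block 19 genes were called. Leaving out 1 array gave 39 to 1267, without wild type heart c and without knockout heart c; 61 without knockout heart a, 73 without b, 40 without wild type heart b, 48 without knockout kidney b, and 62 and 44 without wild type kidneys a and b.

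Genes called in the same direction in both tissues were 1 up and 4 down, of 16209 genes tested in both, where 0.0244 and 0.00907 would be shared by chance (hypergeometric p of 0.0241 and 7.3e-11). H2-Eb1 was the one raised. BC023719 (at least 13.9-fold in heart and 27.4-fold in kidney), 5430410E06Rik (-3.92 ± 0.17 and -3.46 ± 0.41), H2-Ea and Slc29a1 were lower. Slc29a1 is the targeted gene, and H2-Eb1, H2-Ea and BC023719 lie on its chromosome. The hypergeometric test takes genes as independent, so its p does not measure a shared response to the knockout. A further 3 genes were called in opposite directions.

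Of the tested genes of chromosome 17, which carries Slc29a1, 1.93% were called in heart, where chromosome 5 followed with 1.61%, and 1.25% in kidney, where chromosome 19 followed with 0.191%. Among the 50 tested genes on each side, 4 of 100 were called in heart against 82 of 14136 on other chromosomes (one-sided Fisher's exact p of 0.0031). They were H2-Bl (2.16 ± 0.21), BC023719, Pla2g7 (-1.17 ± 0.16) and Guca1a (-2.99 ± 0.39). With the letters as a replicate block Pla2g7 and Guca1a were no longer called, so this count and its exact p rest on the fit without that block. H2-Bl is placed by the order of the gene table, and its probe has no position on chromosome 17 in build mm7. In kidney 1 of 100 was called, BC023719, against 3 of 13979 (exact p of 0.0281). Over the whole chromosome the counts were 13 of 726 in heart (exact p of 7.0e-04) and 8 of 717 in kidney (exact p of 4.5e-09). In heart those were the 4 of the window, Plg, Dnah8, Cyp4f14, Col11a2, H2-Eb1, H2-Ea, Hspa1a, Apom and Trem1. Plg is also a called member of the list of liver transcripts described below, so the heart count is not free of that pattern. In kidney those were H2-Q8, Cyp4f41-ps, H2-Aa, H2-Eb1, H2-Ea, Agpat1, Lta and BC023719. The probes of H2-Eb1, H2-Ea, Agpat1, Lta and H2-Q8 lie between positions 32392430 and 33492642 of build mm7. Fisher's exact test takes genes as independent. Its p-values here therefore do not allow for neighbouring genes that change together, and do not measure an effect along the whole chromosome. With windows of 25 genes the share did not differ (exact p of 0.255 in heart and 1 in kidney), and with no filter on dim probes no gene of the window was called in either tissue (exact p of 1).

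**Figure D4:**
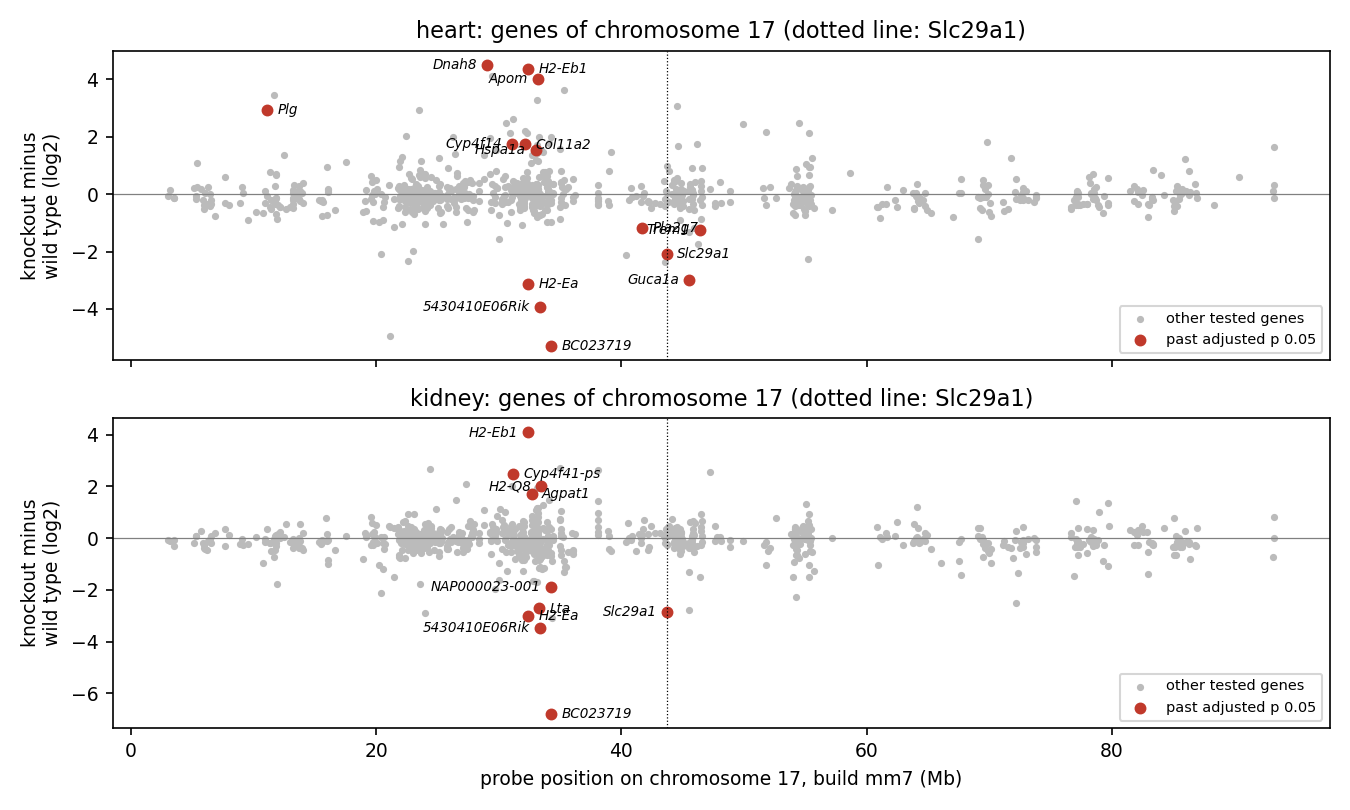
Change between knockout and wild type (log2) of each tested gene of chromosome 17 by probe position in build mm7 (Mb), in heart (top) and kidney (bottom). Red points are called genes and grey points the other tested genes, and the dotted line marks Slc29a1. H2-Eb1 rises and H2-Ea and BC023719 fall in both tissues.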

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

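The tests below of a kept chromosome segment, antigen-presenting cells, sex, genotype, liver tissue, kidney RNA and thymus tissue were all chosen after the results they address had been seen, and that of thymus tissue before its own value was. Those of the segment, sex on chromosome 17, liver tissue and kidney RNA replaced earlier versions, of which the one of sex had been written before its result was seen.

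The knockout effect in heart and kidney differed by the test of the difference itself for 16 named genes. Mbl2 differed by 5.33, Aadac by 4.72, Oas1d by 4.07, Dnah8 by 3.99, Cyp2c40 by 3.83, Fgg by 3.60, Fbp1 by 3.40, Apoc3 by 3.39, Bhmt2 by 3.22, Amn by 2.99, Ugt3a1 by 2.99, Apom by 2.85 and Kap by 2.54 log2 units, all with the higher change in heart. Igkv2-116 differed by 5.5. Vmn1r90 (-2.03) and Psca (-1.91) differed the other way. Mbl2, Aadac, Oas1d, Cyp2c40, Bhmt2, Ugt3a1, Apom and Kap were above background on no wild type heart, Dnah8, Oas1d and Vmn1r90 on no kidney, and Psca on no heart. Apoc3 was above background on 1 of 3 wild type hearts. For all of these the size of the difference is not measured.

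Gene lists whose shift differed with camera between the tissues had these medians of heart minus kidney: cell cycle 2.44, thymus and lymphocytes 2.25, sex-dependent kidney genes 1.03, MHC genes 0.76, inflammatory cytokines and adhesion 0.63, kidney injury 0.58, macrophages and neutrophils 0.49, heat shock and the unfolded protein response 0.32 and interferon response 0.26. Lower in heart were glomerulus (-0.72), endothelium (-0.44), hypoxia response (-0.30) and oxidative stress with NRF2 targets (-0.14). None of the 13 passed with an estimated correlation, where the adjusted p ran from 0.560 to 0.737.

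Genes of chromosome 17 were over-represented among the called genes, and several are MHC genes. A different number of antigen-presenting cells does not by itself account for H2-Eb1 and H2-Aa, which such cells express together. In kidney their changes lay 6.35 log2 units apart, in opposite directions. Both genes had been called in kidney before this test was written. For the other genes such a difference stays open, since most MHC genes and most macrophage and neutrophil genes were lower in knockout kidneys. The sex of the animals is argued against in kidney: among genes called from the kidneys without Xist signal, the neighbours of Slc29a1 were still over-represented (one-sided Fisher's exact p of 3.6e-05). That p takes genes as independent as well. In heart sex cannot be told apart, since that test (exact p of 0.0211) rests on 1 knockout array. A chromosome segment of another strain, kept around the targeted gene through breeding, is a candidate explanation that stays open. Of 15 genes of the chromosome called in 1 tissue only, 86.7% went the same way in the other, against 60.0% of 85 elsewhere (two-sided Fisher's exact p of 0.0773). Both shares count genes without signal above background in the other tissue, such as Dnah8 on the chromosome and Oas1d elsewhere. For such genes the direction there is not measured, so the shares do not decide the question. An effect of the lost transporter on these genes was not tested.

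Liver transcripts were higher in the knockout hearts. Kidney RNA, or signal from the kidney array on the same slide, is argued against by the share it would need: the 19 called liver transcripts stood at a median of -0.58 log2 units relative to the highest kidney, with the lowest at -7.84, where the kidney markers allow at most -12.59. Of 17 transcripts bright in wild type kidney, 6, such as Acsm2, stayed within 1 log2 unit of the wild type hearts on all 3 knockout hearts, and 6, such as Kap, rose by more on all 3. Liver tissue carried over when the samples were taken is a candidate explanation that stays open. A list of 42 liver transcripts written afterwards holds 13 called ones, and of its 15 low members that were neither called nor in the fixed lists 66.7% lay higher on every knockout heart than on every wild type heart. The same list had medians of 1.28, 0.59 and 0.13 on knockout kidneys a, b and c, and of its 42 genes 12 are not low in wild type hearts. Sex cannot be told apart as a source, since only knockout heart c lacks Xist signal, where the called members had a median change of 3.37, nor can slide and genotype.

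Cell cycle, thymus and lymphocyte genes were higher in knockout hearts a and b. Thymus tissue, which lies above the heart, is a candidate source. A list of thymocyte and thymus stroma genes was written after the fixed list was seen and before its own values were. It had median changes of 3.71 on knockout heart a and 4.42 on b (mean of these medians 4.06), and 0.14 on c. B-cell genes had medians of 1.03 and 0.79 on a and b, and 0.46 on c. Of its 29 measured genes 25 are low in wild type hearts; Dntt and Cd8a, abundant in thymus, stood at 6.71 and 4.75 on knockout heart b. Whether genotype or sex plays a part cannot be told apart, because knockout heart c is 1 array (median 0.29 over the fixed list) and 0 wild type hearts carry Xist signal.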

How the results depend on the processing

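The fits with sex as a covariate, with only the arrays without Xist signal, with normexp without the spots of bright local background, and with the value table as named were chosen after seeing the data. The others were planned. The fall of Slc29a1 kept its direction in every fit except the value table with its columns as named, where it was 2.08 in heart and 2.86 in kidney. In heart its adjusted p in limma lay above 0.05 with quantile scaling (-2.04), with no filter or a filter on every array (-2.08 in both), with the letter block (-2.08), and with sex as a covariate or only the arrays without Xist signal (-1.71 in both). It did so without knockout heart a (-2.18) and without wild type heart a (-2.13), b (-2.09) or c (-2.02). In kidney this was so with normexp (-2.22), the letter block (-2.85), and without wild type kidney a (-2.83) or c (-2.77). With 1 array left out the change ran from -2.26 (knockout heart c) to -1.79 (knockout heart b) in heart, and from -2.95 (wild type kidney b) to -2.77 in kidney.

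Heart genes called numbered 17 with normexp, 21 without its bright spots, 60 with quantile scaling, 55 with no filter, 27 with the filter on every array, 205 in the joint fit, 55 with the letter block, 46 without the arrays with Xist signal and 249 at an adjusted p under 0.10. Leaving out knockout heart a, b or c gave 50, 62 and 1979, and wild type heart b or c 23 and 31. Kidney genes numbered 0 with normexp, 60 without its bright spots, 104 with median scaling, 11 with the value table, 4 with no filter, 50 with probe means, 82 with a variance trend, 77 in the joint fit, 289 with the slide block, 2 with the letter block, 121 with sex as a covariate, 121 without the array with Xist signal and 163 at an adjusted p under 0.10. Leaving out knockout kidney a, b or c gave 121, 5 and 87, and wild type kidney a, b or c 1, 2 and 1. In kidney only knockout a carries Xist signal, so sex as a covariate amounts to leaving it out. The counts of 121 are thus the same fit and no separate adjustment for sex. In heart only knockouts a and b carry Xist signal, so with sex as a covariate the knockout effect rests on knockout heart c alone. The effect sizes are those of the fit with only the hearts without Xist signal, so the covariate is no separate check there either. Normexp failed on knockout kidney c, where 7 spots had a bright local background.

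Averaged over tissues, 12 genes were called with normexp, 65 without its bright spots, 98 with no filter, 111 with the filter on every array, 79 with the slide block and 76 with sex as a covariate. Without knockout hearts a, b and c the counts were 94, 125 and 1254, without wild type hearts 114, 73 and 113, without knockout kidney b 112, and without wild type kidneys 86, 116 and 121. The difference between tissues gave 0 genes with normexp, 48 without its bright spots, 46 with the filter on every array, 19 with the slide block and 17 with genotype and letter as a fixed block. That block takes heart and kidney of a letter as 1 mouse, which Xist rules out for knockout b, present in the heart and not in the kidney. Without knockout hearts it gave 61, 73 and 1267, without wild type hearts b and c 40 and 39, without knockout kidney b 48, and without wild type kidneys a and b 62 and 44.

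Heart lists past the threshold numbered 8 with sex as a covariate, 9 without the arrays with Xist signal, 0 with an estimated correlation and 1 with fry. Kidney lists numbered 7 with normexp, 0 with an estimated correlation and 2 with fry. Genes called in both tissues numbered 0 with normexp, 11 with median scaling, 2 with no filter, 3 with the filter on every array, 8 with every probe, 12 with a variance trend and 16 at an adjusted p under 0.10. For neighbours of Slc29a1 the exact p was 0.255 in heart and 1 in kidney with 25 genes on each side, 1 in both with no filter, and 0.0572 in kidney for genes with an unadjusted p under 0.01. Heart and kidney markers lay 9.40 and 9.54 apart with normexp, and kidney markers 14.23 apart with quantile scaling.

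Some directions turned. With sex as a covariate and without the arrays with Xist signal, oxidative phosphorylation in heart was at 0.00435 and the test of extracellular matrix (-0.0228) pointed up. With normexp, Grin2c (0.0789), Lta (0.32), Oosp1 (0.63) and H2-Ea (0.62) turned in kidney, Gabrb2 (0.15), Mir124-2hg (0.30) and H2-Ea (0.14) in the average, and Cyp2c40 (-0.0221) in the difference. Without its bright spots Apom (-0.24) turned in the difference. Equal letters correlated at -0.179 to 0.175 in kidney, where 2 of 6 arrays were closest to their own letter. Between heart and kidney they did so at -0.0162 to 0.0443 in knockouts and -0.0828 to 0.00432 in wild types. With the letter block 32 of the 116 heart genes were still called, and all 20 heart lists passed.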

Other observations

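Several clock genes separated knockout kidneys b and c from the other kidneys. Dbp, a clock output gene, stood at 2.07 and 2.15 on those arrays and at 6.09 on knockout kidney a, and at 6.08 to 6.80 in wild types. Ciart stood at -9.03 and -8.93 against -3.46, and at -3.39 to -2.92 in wild types. Arntl, which peaks when Dbp is low, stood at 1.0 and 1.3 against -1.64, and at -2.47 to -1.49 in wild types. Knockout heart b was shifted the same way, with Ciart at -6.21 where the other hearts lay at -3.99 to -3.35, and Arntl at 1.28 where they lay at -0.31 to 0.26. The circadian list did not pass with camera in either tissue (adjusted p of 0.061 in heart and 0.780 in kidney). That test asks for a shift in a common direction, while members such as Arntl and Dbp moved in opposite directions. It therefore cannot decide whether the clock was shifted. In kidney Nfil3 (2.52 ± 0.46, SE, n = 3 and 3), Cry1 (1.3 ± 0.21) and Nr1d1 (-0.56 ± 0.15) passed adjusted over the list alone. These genes lay outside the wild type range on knockout kidney a as well. Nfil3 stood there at -0.16 (wild types -1.92 to -1.22), Cry1 at -4.01 (-5.60 to -4.94) and Nr1d1 at 0.14 (0.53 to 0.71).

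Single arrays carried other tissues' marker genes. The surfactant gene Sftpc stood at 6.46 on knockout heart a and at most at -3.91 on the other hearts. Star, of steroid-making cells, stood at 0.63 on knockout kidney a and at most at -5.67 on the other kidneys. On the same kidney, the one with Xist signal, Prlr stood at 0.58 and Slc7a12 at 4.63, and Cyp2j13 at -5.46 where the other kidneys lay at 5.37 to 6.60. Of the adipose list, 11 of 14 members were higher in knockout hearts (median 1.27, adjusted p of 0.046 with camera, and adjusted p = 0.663 with an estimated correlation), with 1.73 on wild type heart a as well.

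The series text gives 3 knockout and 3 wild type mice as the source of both tissues, and the labels do not say which arrays share an animal. Among the knockouts, 2 hearts and 1 kidney carried Xist signal, so these hearts and kidneys cannot all come from the same 3 animals.

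Counts were compared with those of other splits of the same arrays. In heart the real split gave 116 genes and 20 lists, and the highest of the others 2 genes and 20 lists; in kidney 28 genes and 13 lists, and the highest of the others 0 genes and 20 lists. With 10 splits per tissue no share can fall under 0.05. As many calls as in the real split came from 1 split for heart genes, 2 for heart lists, 1 for kidney genes and 3 for kidney lists. Of the 4 heart splits that part every letter, the 3 others gave at most 0 genes and 10 lists. Over both tissues 79 splits part every heart letter, leaving out the real one with the kidneys exchanged, which swaps the counts of the average and the difference. Of these 1, the real one, gave 192 or more genes for the average and 1 gave 117 or more for the difference, with 49 the highest other for both. Chance is not excluded by this, because the pairing of the letters was read from the same data. The exchanged split that was left out gave 192 genes for the difference. The 79 splits were chosen after seeing the data. A first choice had kept the exchanged split, which gave more genes for the difference than the real one.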
